A study of Rattus norvegicus with 30 samples.

How the data were processed

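Gene expression was measured in heart tissue of male Wistar Han rats (Crl:WI(Han)) that received a single dose of isoproterenol hydrochloride, a synthetic catecholamine that activates beta-adrenergic receptors, or vehicle. Per the labels' protocols, tissue taken at necropsy was stored in RNAlater, total RNA was extracted with a Qiagen RNeasy kit, and biotinylated cRNA was made from 10 ug of total RNA with the standard Affymetrix protocol and hybridised to rat RAT230_2 arrays, which have 1 colour. The dose is given in the labels as 0.5 with the unit mg/kg/ml and in the design text as 0.5 mg, so the dose per body weight is not settled here. The labels place the last sampling at 72 h, while the design text gives 48 h; the labels are followed throughout. Each array is titled a biological replicate. Whether each came from its own animal is not given in the sources used here, and if some did not, the p-values measure only the spread between these samples.

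The deposited table holds linear intensity values, 1 per probe set and array, for 31099 probe sets on 30 arrays. The summarisation algorithm and any scaling by the authors are not given in the sources used here. The deposited intensity values reach 15512, 29 of them equal 0, and none is negative. Array medians of the intensity lay between 21.2 and 70.4, a range of 3.32-fold, so the arrays had not been brought to a common median. Between 21.8% and 43.0% of probe sets lay below an intensity of 16 on an array. Total signal per array lay between 3999398 and 11952353. No 2 arrays held identical values, and the correlation of normalized log2 values between arrays of the same group lay between 0.934 and 0.984. Every per-sample column was matched to a sample by its label.

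Values were taken as log2(intensity + 16). Array medians on that scale spanned 1.22, above the limit of 0.5 set beforehand, so the arrays were quantile normalized, which gives every array the same distribution of values. Fold changes are therefore on the log2(intensity + 16) scale, which understates the change of dim probe sets, and a change shared by most transcripts of an array is removed. After 57 control probe sets were left out, probe sets that reached the 40th percentile of all values, an intensity of 23, in at least 3 arrays were kept, which left 24292. limma fitted 8 group means (treatment by time) to all 30 arrays, with 22 residual degrees of freedom and an intensity trend in the empirical Bayes step. Tests were two-sided limma moderated tests, adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05 on the adjusted p. The contrasts were isoproterenol against vehicle at 1, 3, 24 and 72 h, the difference of that effect between successive times, a moderated F test among the 4 vehicle groups, and a moderated F test of any isoproterenol effect. With 3 to 5 arrays per group, the number of arrays limits the precision. Values after ± are standard errors of log2 changes unless SD is written.

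Probe sets were named through a table of platform annotation, with symbols updated through current gene records: 20758 symbols through the gene number, 2 through an accession, and 66 kept as listed. Of the probe sets that are not controls, 20826 had 1 gene, 436 had several and were not named, and 9780 were not listed in that table and are unnamed here. Of those tested, 17584 had 1 gene, for 12451 genes. Where a gene had several probe sets, the one with the highest mean log2 value over all arrays stood for it.

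The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. There were 29 lists with 831 genes, of which 730 were measured: immediate early genes; cAMP and CREB targets; beta-adrenergic signalling; cytokines, chemokines and adhesion; extracellular matrix and remodelling; hypertrophy and fetal genes; fatty acid oxidation and lipid use; oxidative phosphorylation; glycolysis; cell cycle. The lists also covered heat shock proteins, endoplasmic reticulum stress, oxidative stress and metallothioneins, ion channels and transporters, p53 targets and apoptosis, circadian clock, interferon response, hypoxia and angiogenesis, and glucocorticoid targets. Cell type lists were neutrophil, monocyte and macrophage, cardiomyocyte sarcomere, endothelial, fibroblast and mural cell, erythroid, adipocyte, lymphocyte and mast cell, skeletal muscle, and atrial, mesothelial and nerve markers. Some genes stand in more than 1 list, such as Nr4a1 among the immediate early genes and the CREB targets. Each list was tested at each time with limma's camera at a preset correlation of 0.01, adjusted over all 116 tests, of which 46 passed. With an estimated correlation between genes, 19 passed. The fry test, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, passed 52.

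Named genes were, at each time, the 10 with the largest rise and the 10 with the largest fall among those past the threshold whose isoproterenol arrays all lay on 1 side of all vehicle arrays of that time, leaving out predicted or uncharacterised symbols. They also included up to 4 members with the smallest adjusted p of each list with a call at that time, and 20 genes at every time whatever their values (Fos, Egr1, Nr4a1, Atf3, Il6, Ccl2, Nppa, Nppb, Timp1, Spp1, Postn, Col1a1, S100a9, Hmox1, Ucp3, Pdk4, Adrb1, Pln, Myh6 and Myh7). For each difference between times, the 3 genes with the largest rise and the 3 with the largest fall were named, and for the vehicle arrays the 10 with the smallest adjusted p and the circadian clock list.

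The alternatives were other pseudocounts (1 and 64), no normalization, centring on array medians, no filter, a filter at the 60th percentile, no intensity trend, robust variance, array weights, a fit to only the arrays compared, a replicate block, a 2-fold threshold, the mean of a gene's probe sets, and leaving out each array in turn. After the data were seen, scaling to a common trimmed mean, a filter on normalized values, the GAPDH 3' minus 5' difference as a covariate, and leaving out 2 arrays that stood apart were added. Replicate numbers were not used to pair arrays.

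The pipeline was tested on simulated data for 24292 probe sets with 100 changed at each size. At a log2 change of 1, it recovered 67% of them at 1 h, 55% at 3 h, 55% at 24 h and 64% at 72 h. At a log2 change of 2, it recovered 95%, 96%, 97% and 98% in the same order. Between 2.41% and 6.21% of calls were false in that simulation. It drew independent normal noise for each probe set, with no brightness differences between arrays and no array standing apart. These rates are therefore not the error rates of the calls reported below. Analyses used R 4.3.3, limma 3.58.1, data.table (1.17.8), Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.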

Results

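Hearts were sampled 1, 3, 24 and 72 h after a single dose of isoproterenol or vehicle. The vehicle groups had 3 arrays at each time, and the isoproterenol groups had 5, 4, 4 and 5 arrays in order of time. Of the 24292 probe sets tested, 7769 passed the moderated F test for an isoproterenol effect at any time. Isoproterenol arrays carry numbers from 33 to 62 and vehicle arrays from 4 to 21, so array order and treatment cannot be told apart. The largest rises and falls named below are those among genes whose isoproterenol arrays all lay on 1 side of all vehicle arrays of the time, which was the condition for naming them.

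**Figure D1:**
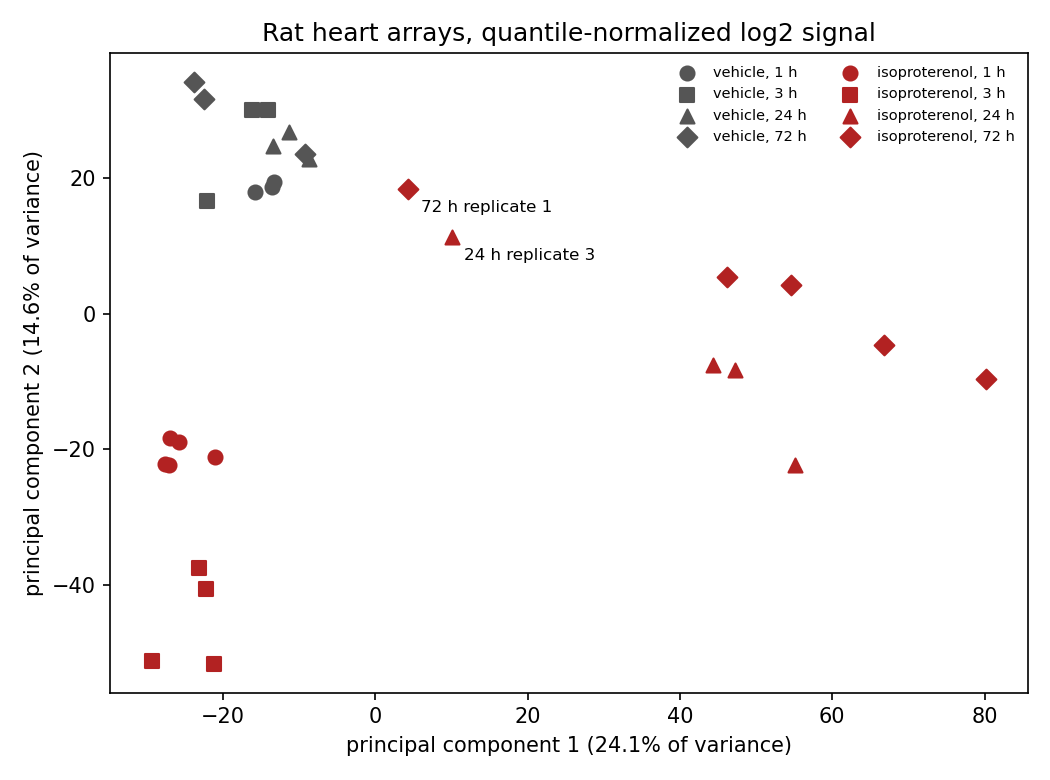
Principal components of the quantile-normalized log2 signal, 1 point per array, with the percent of variance on each axis. Colour gives the treatment and shape the time. Component 1 held 24.1% of the variance and component 2 held 14.6%. Isoproterenol replicate 3 at 24 h (10.0) and replicate 1 at 72 h (4.29) lay on component 1 between the vehicle arrays and the other isoproterenol arrays of their times (44.3 to 55.2 at 24 h and 46.1 to 80.2 at 72 h).

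At 1 h the largest rises included transcription factors of the immediate early class and the cytokine gene Il6. Fosb, a subunit of the AP-1 transcription factor, rose by 5.69 ± 0.26 on the log2 scale (51.6-fold, limma adjusted p = 7.23e-16, n = 5 and 3). The orphan nuclear receptors Nr4a3 and Nr4a2 rose by 4.92 ± 0.40 and 4.21 ± 0.26, and Il6, an inflammatory cytokine, by 4.69 ± 0.38 (25.8-fold, adjusted p = 2.72e-10). Vehicle levels of Fosb (5.27 ± 0.424, SD, n = 3), Il6 (4.58 ± 0.332), Cxcl1, Ptgs2, Socs3, S100a9 and Il1r2 and the isoproterenol level of Hlx were as dim as the probe sets the filter leaves out, so the sizes of their changes at 1 h are best read as lower bounds. The largest falls were in Aplnr, the apelin receptor (-2.72 ± 0.31, adjusted p = 2.51e-07), and Hlx, a homeobox transcription factor (-2.23 ± 0.23).

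Of 27 measured immediate early genes, 20 rose, 0 fell and 7 did not pass, against 21 rising and 0 falling adjusted over the list alone (camera adjusted p = 4.53e-54). Atf3, a transcription factor induced by stress, rose by 3.38 ± 0.37, Nr4a1 by 2.86 ± 0.27, Fos by 2.81 ± 0.44 and the zinc finger factor Egr1 by 2.35 ± 0.35. Of 21 cAMP and CREB targets, 12 rose, 0 fell and 9 did not pass, against 17 rising and 0 falling adjusted over the list alone (camera adjusted p = 6.24e-34). Crem, which encodes cAMP-responsive activators and repressors, rose by 2.98 ± 0.17 and the phosphodiesterase gene Pde10a by 2.18 ± 0.20. Of 35 cytokine, chemokine and adhesion genes, 13 rose, 0 fell and 22 did not pass, against 13 rising and 0 falling adjusted over the list alone (camera adjusted p = 1.79e-14). Among them were Cxcl1, a chemokine for neutrophils (3.63 ± 0.35), the prostaglandin synthase Ptgs2 (2.94 ± 0.32), the feedback inhibitor Socs3 (2.60 ± 0.28) and the monocyte chemokine Ccl2 (2.16 ± 0.41). Of 7 neutrophil markers, 2 rose, 0 fell and 5 did not pass, against 3 rising and 0 falling adjusted over the list alone (camera adjusted p = 0.000404). S100a9 rose by 1.42 ± 0.35 and the decoy receptor Il1r2 by 1.34 ± 0.29, while S100a8 did not pass (0.82 ± 0.30). S100a9 did not pass without vehicle replicate 3 (1.00, limma adjusted p = 0.300), vehicle replicate 1 (0.0581) or isoproterenol replicate 2 (0.0609), nor Il1r2 without vehicle replicate 3 (0.0702).

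Stress and growth lists also shifted upward at 1 h. Of 25 oxidative stress and metallothionein genes, 5 rose, 0 fell and 20 did not pass, against 5 rising and 0 falling adjusted over the list alone (camera adjusted p = 0.00377). Sulfiredoxin (Srxn1) rose by 3.48 ± 0.26, metallothionein Mt2A by 2.55 ± 0.46 and heme oxygenase Hmox1 by 1.33 ± 0.37. Hmox1 did not pass in any of the 8 fits that left out 1 array of 1 h (limma adjusted p 0.0596 to 0.293), nor with a pseudocount of 64, no filter, no intensity trend, robust variance, a replicate block or trimmed mean scaling (0.0531 to 0.0807). Of 19 glucocorticoid targets, 7 rose, 2 fell and 10 did not pass, against 9 rising and 2 falling adjusted over the list alone (camera adjusted p = 2.32e-06). Errfi1, an inhibitor of the EGF receptor, rose by 2.76 ± 0.30 and Angptl4, an inhibitor of lipoprotein lipase, by 1.98 ± 0.38. Of 21 p53 and apoptosis genes, 4 rose, 0 fell and 17 did not pass, against 6 rising and 0 falling adjusted over the list alone (camera adjusted p = 0.00897). Gadd45g rose by 2.06 ± 0.24 and the cell cycle inhibitor Cdkn1a by 1.91 ± 0.25. Plk2 rose by 0.88 and did not pass without any 1 isoproterenol array or vehicle replicate 2 or 3 (limma adjusted p 0.0502 to 0.259). Of 22 hypertrophy and fetal genes, 3 rose, 0 fell and 19 did not pass, against 3 rising and 0 falling adjusted over the list alone (camera adjusted p = 1.52e-05, adjusted p = 0.0498 with an estimated correlation). The actin-binding Xirp1 rose by 2.31 ± 0.16 and tubulin Tubb6 by 1.47 ± 0.39. Tubb6 did not pass without any 1 vehicle array or isoproterenol replicate 1, 3 or 4 (limma adjusted p 0.0587 to 0.163), nor with a pseudocount of 64, no intensity trend, robust variance or a replicate block (0.0539 to 0.0697). Gdf15 rose by 0.92. It did not pass without vehicle replicate 1 or 2 or isoproterenol replicate 1, 3, 4 or 5 (limma adjusted p 0.0767 to 0.46).

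Of 20 heat shock protein genes, 5 rose, 0 fell and 15 did not pass, against 5 rising and 0 falling adjusted over the list alone (camera adjusted p = 5.84e-05, adjusted p = 0.0705 with an estimated correlation). The chaperones Hspa1a and Dnajb1 rose by 2.40 ± 0.34 and 2.09 ± 0.38. Of 25 endoplasmic reticulum stress genes, 3 rose, 0 fell and 22 did not pass, against 5 rising and 0 falling adjusted over the list alone (camera adjusted p = 0.0195, adjusted p = 0.518 with an estimated correlation). Cebpb, a transcription factor, rose by 1.87 ± 0.24. Of 25 beta-adrenergic signalling genes, 2 rose, 0 fell and 23 did not pass, against 3 rising and 0 falling adjusted over the list alone (camera adjusted p = 0.0223, adjusted p = 0.104 with an estimated correlation). Rgs2, which limits G protein signals, rose by 2.81 ± 0.27. Prkar2b rose by 0.83 (0.825) and did not pass without vehicle replicate 2 (limma adjusted p = 0.052) or 3 (0.0662). Of 46 cell cycle genes, 1 rose, 0 fell and 45 did not pass, against 1 rising and 0 falling adjusted over the list alone (camera adjusted p = 0.0441, adjusted p = 0.720 with an estimated correlation). The cell cycle shift was downward, with a median of -0.25, although the replication clamp Pcna rose by 0.73 ± 0.17 (limma adjusted p = 0.0867 without vehicle replicate 2). Timp1, an inhibitor of matrix metalloproteinases, rose by 2.58 ± 0.51. Pdk4, an inhibitor of pyruvate dehydrogenase, rose by 1.20 ± 0.29, and did not pass with a replicate block (limma adjusted p = 0.0524) or without vehicle replicate 1 (0.0537) or 3 (0.136). Spp1 (0.24 ± 0.55), Postn (0.06 ± 0.54), Col1a1 (-0.23 ± 0.33) and Ucp3 (-0.05 ± 0.27) did not pass at 1 h. The receptor Adrb1 (0.34 ± 0.22), the calcium pump inhibitor Pln (0.00 ± 0.08), the myosin heavy chains Myh6 (-0.12 ± 0.07) and Myh7 (0.49 ± 0.29), and the natriuretic peptide genes Nppa (0.89 ± 0.49) and Nppb (0.29 ± 0.23) did not pass.

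In all, 643 probe sets passed at 1 h, 445 higher and 198 lower, for 318 and 140 genes. The count was 411 without vehicle replicate 1 and 392 without vehicle replicate 3. Without normalization it was 190, with 134 higher and 56 lower, the median of all probe sets was -0.23, and the beta-adrenergic median turned from 0.20 to -0.06. The list medians then turned to -0.08 for heat shock, -0.13 for endoplasmic reticulum stress, -0.16 for oxidative stress and -0.22 for p53 genes, with 2, 1, 2 and 2 members higher. The hypertrophy list had 1 higher (median 0.11 against 0.32), glucocorticoid targets 4 higher and 1 lower, neutrophil markers 1, beta-adrenergic genes 1 and cell cycle genes 0 higher. The beta-actin 3' minus 5' log2 difference, a measure of RNA integrity, was 1.82 ± 0.206 (SD, n = 5) in isoproterenol arrays and 1.53 ± 0.0556 (SD, n = 3) in vehicle arrays. The same difference for GAPDH was 0.438 ± 0.0604 (SD) and 0.4065 ± 0.0666 (SD).

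At 3 h the largest rises were in immediate early genes and in single genes such as Mt2A, Timp1 and Angptl4. The oxidative stress and metallothionein, matrix and lipid lists had no camera call (adjusted p = 0.0739, 0.496 and 0.811). Nr4a3 rose by 5.97 ± 0.41 (62.9-fold, adjusted p = 4.92e-12, n = 4 and 3), Fosb by 4.97 ± 0.27 and Fos by 4.61 ± 0.46. The vehicle level of Fos was 5.54 ± 0.309 (SD, n = 3) at 3 h and 8.57 ± 0.258 at 1 h, so its larger change at 3 h came with a lower vehicle level. Mt2A rose by 4.28 ± 0.48, Timp1 by 4.26 ± 0.54, Angptl4 by 4.01 ± 0.40 and the sphingosine kinase gene Sphk1 by 3.98 ± 0.25. The largest falls were in Nxpe1 (-2.76 ± 0.28), the cardiac gene Lrrc10 (-2.62 ± 0.19, adjusted p = 1.05e-11), Aplnr (-2.25 ± 0.32) and Klf15, a repressor of cardiac growth genes (-2.10 ± 0.24). At 3 h the vehicle levels of Fosb, Angptl4, Sphk1, Cxcl1, Il6, Ccl7, Il1r2 and S100a8 and the isoproterenol level of Nxpe1 were as dim as the probe sets the filter leaves out, and their changes too are lower bounds in this sense.

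Of 27 immediate early genes, 23 rose, 0 fell and 4 did not pass, against 24 rising and 0 falling adjusted over the list alone (camera adjusted p = 2.22e-34). Atf3 rose by 4.08 ± 0.38, Egr1 by 3.55 ± 0.37 and Nr4a1 by 1.91 ± 0.28. Of 21 cAMP and CREB targets, 14 rose, 0 fell and 7 did not pass, against 14 rising and 0 falling adjusted over the list alone (camera adjusted p = 5.91e-18). Crem rose by 3.59 ± 0.17 and the cAMP phosphodiesterase gene Pde4b by 2.28 ± 0.18. Of 35 cytokine, chemokine and adhesion genes, 17 rose, 1 fell and 17 did not pass, against 17 rising and 1 falling adjusted over the list alone (camera adjusted p = 1.32e-11). Cxcl1 rose by 3.88 ± 0.37, Ccl2 by 3.48 ± 0.43, the monocyte chemokine Ccl7 by 3.45 ± 0.40 and Il6 by 3.35 ± 0.40. Of 7 neutrophil markers, 4 rose, 0 fell and 3 did not pass, against 4 rising and 0 falling adjusted over the list alone (camera adjusted p = 0.000199). They were Il1r2 (2.30 ± 0.30), S100a9 (2.06 ± 0.37), S100a8 (1.91 ± 0.32) and Lcn2 (0.96 ± 0.26). Without vehicle replicate 3 Lcn2 was at 0.54 and did not pass (limma adjusted p = 0.151), nor with only the arrays compared in the fit (0.114).

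Of 22 hypertrophy and fetal genes, 9 rose, 0 fell and 13 did not pass, against 12 rising and 0 falling adjusted over the list alone (camera adjusted p = 2.27e-07). Tubb6 rose by 2.79 ± 0.41, Xirp1 by 2.69 ± 0.17, the growth factor Hbegf by 2.28 ± 0.30 and Nppb by 0.76 ± 0.24, while Nppa did not pass (0.04 ± 0.51). Nppb did not pass without vehicle replicate 2 or 3 or isoproterenol replicate 1, 3 or 4 (limma adjusted p 0.0613 to 0.183), nor with array weights, no intensity trend or a replicate block (0.0530 to 0.153). Of 20 heat shock protein genes, 8 rose, 0 fell and 12 did not pass, against 10 rising and 0 falling adjusted over the list alone (camera adjusted p = 6.70e-06). Hspa1a rose by 3.60 ± 0.36 and Dnajb4 by 1.46 ± 0.14. Of 21 p53 and apoptosis genes, 8 rose, 0 fell and 13 did not pass, against 9 rising and 0 falling adjusted over the list alone (camera adjusted p = 0.00222). Gadd45g rose by 3.06 ± 0.25, the receptor gene Tnfrsf12a by 2.51 ± 0.41 and the survival factor Mcl1 by 1.99 ± 0.22. Of 19 glucocorticoid targets, 10 rose, 1 fell and 8 did not pass, against 12 rising and 3 falling adjusted over the list alone (camera adjusted p = 1.06e-07). Sgk1, a kinase of ion transport, rose by 2.76 ± 0.24 and Errfi1 by 2.95 ± 0.31. Klf15, given above among the largest falls, was the glucocorticoid target that fell.

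Hmox1 rose by 3.13 ± 0.39 at 3 h, and Pdk4 by 1.35 ± 0.30. The uncoupling protein gene Ucp3 fell by 1.05 ± 0.28 and did not pass without vehicle replicate 2 (limma adjusted p = 0.0694) or isoproterenol replicate 3 (0.0536). Adrb1 (-0.27 ± 0.23), Pln (0.00 ± 0.09), Myh6 (0.03 ± 0.08), Myh7 (-0.04 ± 0.31), Col1a1 (-1.01 ± 0.35), Spp1 (-0.06 ± 0.57) and Postn (1.18 ± 0.56) did not pass.

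In all, 2766 probe sets passed at 3 h, 1484 higher and 1282 lower, for 1000 and 949 genes. The split was 1854 higher and 633 lower with arrays centred on their medians. With trimmed mean scaling, chosen after seeing the data, it was 1284 and 2070, at a median of all probe sets of -0.13. Without normalization 478 passed, 295 higher and 183 lower, at a median of -0.19. The lists then had 11 cytokine, 5 hypertrophy, 3 heat shock, 3 p53 and 6 glucocorticoid members higher. Of the 445 probe sets higher at 1 h, 351 were also higher at 3 h, against 27.2 for independent lists. Of the 198 lower at 1 h, 91 were lower at 3 h, against 10.5. The beta-actin 3' minus 5' difference was 1.93 ± 0.147 (SD, n = 4) in isoproterenol arrays and 1.36 ± 0.740 (SD, n = 3) in vehicle arrays. For GAPDH it was 0.411 ± 0.0712 (SD) and 0.401 ± 0.163 (SD).

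At 24 h the largest rises included macrophage and matrix genes. Spp1, which encodes the secreted matrix protein osteopontin, rose by 7.65 ± 0.57 (201-fold, adjusted p = 5.66e-10, n = 4 and 3). The sizes of the changes of Spp1, Il1b and Mmp12 at 24 h are best read as lower bounds, since vehicle Spp1 (4.84 ± 0.725, SD, n = 3), Il1b and Mmp12 were as dim as the probe sets the filter leaves out. Gpnmb, a glycoprotein gene of phagocytes, rose by 4.67 ± 0.49, Timp1 by 4.24 ± 0.54, the lectin gene Lgals3 by 3.74 ± 0.41 and Postn, a matrix protein of activated fibroblasts, by 3.67 ± 0.56. The largest falls were in Cd1d1, which presents lipid antigens (-2.46 ± 0.52), the organic cation transporter Slc22a3 (-2.22 ± 0.36), the protease gene Htra3 (-2.00 ± 0.24) and Apln, which encodes apelin (-1.91 ± 0.27).

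Of 30 monocyte and macrophage markers, 21 rose, 0 fell and 9 did not pass, against 22 rising and 0 falling adjusted over the list alone (camera adjusted p = 6.57e-18, adjusted p = 0.0918 with an estimated correlation). Their median change was 1.85, and the integrin gene Itgb2 rose by 2.45 ± 0.31. Of 46 extracellular matrix genes, 18 rose, 3 fell and 25 did not pass, against 22 rising and 5 falling adjusted over the list alone (camera adjusted p = 1.87e-06, adjusted p = 0.513 with an estimated correlation). The elastase gene Mmp12 rose by 2.72 ± 0.38 and fibronectin (Fn1) by 2.36 ± 0.36, while Col1a1 did not pass (0.69 ± 0.35, adjusted p = 0.210). Of 46 cell cycle genes, 20 rose, 0 fell and 26 did not pass, against 34 rising and 0 falling adjusted over the list alone (camera adjusted p = 2.66e-14, adjusted p = 0.118 with an estimated correlation). Mcm6 and Mcm7 of the replication helicase rose by 1.88 ± 0.25 and 1.47 ± 0.24. Of 25 endoplasmic reticulum stress genes, 14 rose, 0 fell and 11 did not pass, against 14 rising and 0 falling adjusted over the list alone (camera adjusted p = 7.50e-07, adjusted p = 0.118 with an estimated correlation). Sdf2l1 rose by 1.76 ± 0.24 and the disulfide isomerase gene Pdia6 by 0.93 ± 0.15. Of 35 cytokine, chemokine and adhesion genes, 6 rose, 0 fell and 29 did not pass, against 6 rising and 0 falling adjusted over the list alone (camera adjusted p = 0.0128, adjusted p = 0.507 with an estimated correlation). Ccl2 rose by 3.25 ± 0.43 and the inflammasome products Il1b and Il18 by 1.56 ± 0.30 and 1.62 ± 0.34, while Il6 did not pass (0.58 ± 0.40).

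Of 22 hypertrophy and fetal genes, 13 rose, 1 fell and 8 did not pass, against 15 rising and 1 falling adjusted over the list alone (camera adjusted p = 1.06e-07, adjusted p = 0.0201 with an estimated correlation). Tubb6 rose by 3.10 ± 0.41, the atrial natriuretic peptide gene Nppa by 2.75 ± 0.51, the actinin gene Actn1 by 2.24 ± 0.34 and Nppb by 0.76 ± 0.24. With median centring 8 members rose and 1 fell, at a list median of 0.55 against 0.79. Nppb did not pass under median centring, trimmed mean scaling and 4 other settings (limma adjusted p 0.0526 to 0.116), nor without vehicle replicate 2 or 3 or isoproterenol replicate 1 or 2 (0.0808 to 0.220). Hmox1 rose by 1.49 ± 0.39 and did not pass without vehicle replicate 1 (limma adjusted p = 0.0526) or isoproterenol replicate 2 (0.0690). Atf3 rose by 1.25 ± 0.38 and did not pass with a pseudocount of 64 (0.107), nor without vehicle replicate 1 or 3 or isoproterenol replicate 1, 2 or 4 (limma adjusted p 0.0645 to 0.119). Fos (0.67 ± 0.46), Egr1 (0.12 ± 0.37), Nr4a1 (-0.56 ± 0.28), Myh7 (0.60 ± 0.31), Myh6 (-0.01 ± 0.08), Pln (-0.21 ± 0.09), Adrb1 (-0.22 ± 0.23), S100a9 (0.38 ± 0.37), Ucp3 (-0.14 ± 0.28) and Pdk4 (0.87 ± 0.30, adjusted p = 0.0558) did not pass.

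Metabolic, ion channel and sarcomere lists shifted downward at 24 h. Of 40 fatty acid oxidation and lipid genes, 1 rose, 14 fell and 25 did not pass, against 2 rising and 20 falling adjusted over the list alone (camera adjusted p = 7.50e-07, adjusted p = 0.406 with an estimated correlation). Plin5, which coats lipid droplets, fell by 1.34 ± 0.30 and the carnitine palmitoyltransferases Cpt2 and Cpt1b by 0.95 ± 0.20 and 0.75 ± 0.18. Of 47 oxidative phosphorylation genes, 0 rose, 9 fell and 38 did not pass, against 0 rising and 12 falling adjusted over the list alone (camera adjusted p = 1.62e-06, adjusted p = 0.513 with an estimated correlation). Ndufs1, of complex I, fell by 0.59 ± 0.16 and did not pass without vehicle replicate 2 (limma adjusted p = 0.0581) or isoproterenol replicate 2 (0.0973), nor with only the arrays compared (0.0676). Sdhc fell by 0.46 and did not pass without any 1 vehicle array or isoproterenol replicate 1, 2 or 4 (limma adjusted p 0.0557 to 0.102). Of 29 ion channel and transporter genes, 1 rose, 9 fell and 19 did not pass, against 1 rising and 11 falling adjusted over the list alone (camera adjusted p = 0.000330, adjusted p = 0.244 with an estimated correlation). The potassium channel genes Kcnk2 and Kcnip2 fell by 1.66 ± 0.32 and 1.10 ± 0.21. Of 29 sarcomere markers, 2 rose, 7 fell and 20 did not pass, against 2 rising and 8 falling adjusted over the list alone (camera adjusted p = 0.00377, adjusted p = 0.488 with an estimated correlation). Hrc, of the calcium store, fell by 1.12 ± 0.22, while Des and Csrp3 rose by 0.49 ± 0.12 and 0.81 ± 0.10 and did not pass under median centring or trimmed mean scaling. Des did not pass without vehicle replicate 2 (limma adjusted p = 0.0535) or with only the arrays compared (0.0502). With median centring 0 sarcomere markers rose and 17 fell (median -0.51), and with trimmed mean scaling 0 and 5 (-0.50), against a reported median of -0.18. Centring gave 16 lower oxidative phosphorylation members. Of 27 hypoxia and angiogenesis genes, 2 rose, 7 fell and 18 did not pass, against 2 rising and 8 falling adjusted over the list alone (camera adjusted p = 0.0197, adjusted p = 0.244 with an estimated correlation). Vegfb fell by 1.06 ± 0.23 and the VEGF receptor gene Kdr by 0.92 ± 0.19.

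The falls at 24 h are relative to the other transcripts. Isoproterenol arrays were brighter on average, with a median log2 intensity before normalization of 6.19 ± 0.355 (SD, n = 4) against 5.69 ± 0.296 (SD, n = 3). Isoproterenol replicates 1, 2 and 4 were at 6.20 to 6.43. Replicate 3, at 5.68, lay within the vehicle arrays (5.51 to 6.03). Without normalization the median of all probe sets was 0.47, and 3078 probe sets passed as higher and 17 as lower. The list medians were then 0.05 for fatty acid oxidation, 0.21 for oxidative phosphorylation, 0.20 for ion channels, 0.12 for sarcomere markers and 0.32 for hypoxia. Their lower calls were 0, 0, 0, 0 and 1 in the same order, and 12 cytokine and 39 cell cycle members were higher and 0 matrix members lower. The beta-actin 3' minus 5' difference was 0.872 ± 0.372 (SD, n = 4) in isoproterenol arrays and 1.64 ± 0.245 (SD, n = 3) in vehicle arrays. For GAPDH it was 0.298 ± 0.0254 (SD) and 0.381 ± 0.0763 (SD).

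In all, 3165 probe sets passed at 24 h, 1781 higher and 1384 lower, for 1393 and 973 genes. With arrays centred on their medians the split was 1476 and 1890, at a median of all probe sets of -0.16. The count was 2082 without vehicle replicate 2, 1857 without vehicle replicate 3, 1576 without isoproterenol replicate 2 and 2091 without isoproterenol replicate 4. The 2 arrays that stood apart, isoproterenol replicate 3 at 24 h and replicate 1 at 72 h, were also left out, a choice made after seeing the data, and 4778 then passed at 24 h. The lists then had 23 macrophage, 27 matrix, 34 cell cycle, 16 endoplasmic reticulum stress, 13 hypertrophy and 8 cytokine members higher. They had 24 fatty acid oxidation, 22 oxidative phosphorylation, 10 ion channel, 10 sarcomere and 9 hypoxia members lower.

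**Figure D2:**
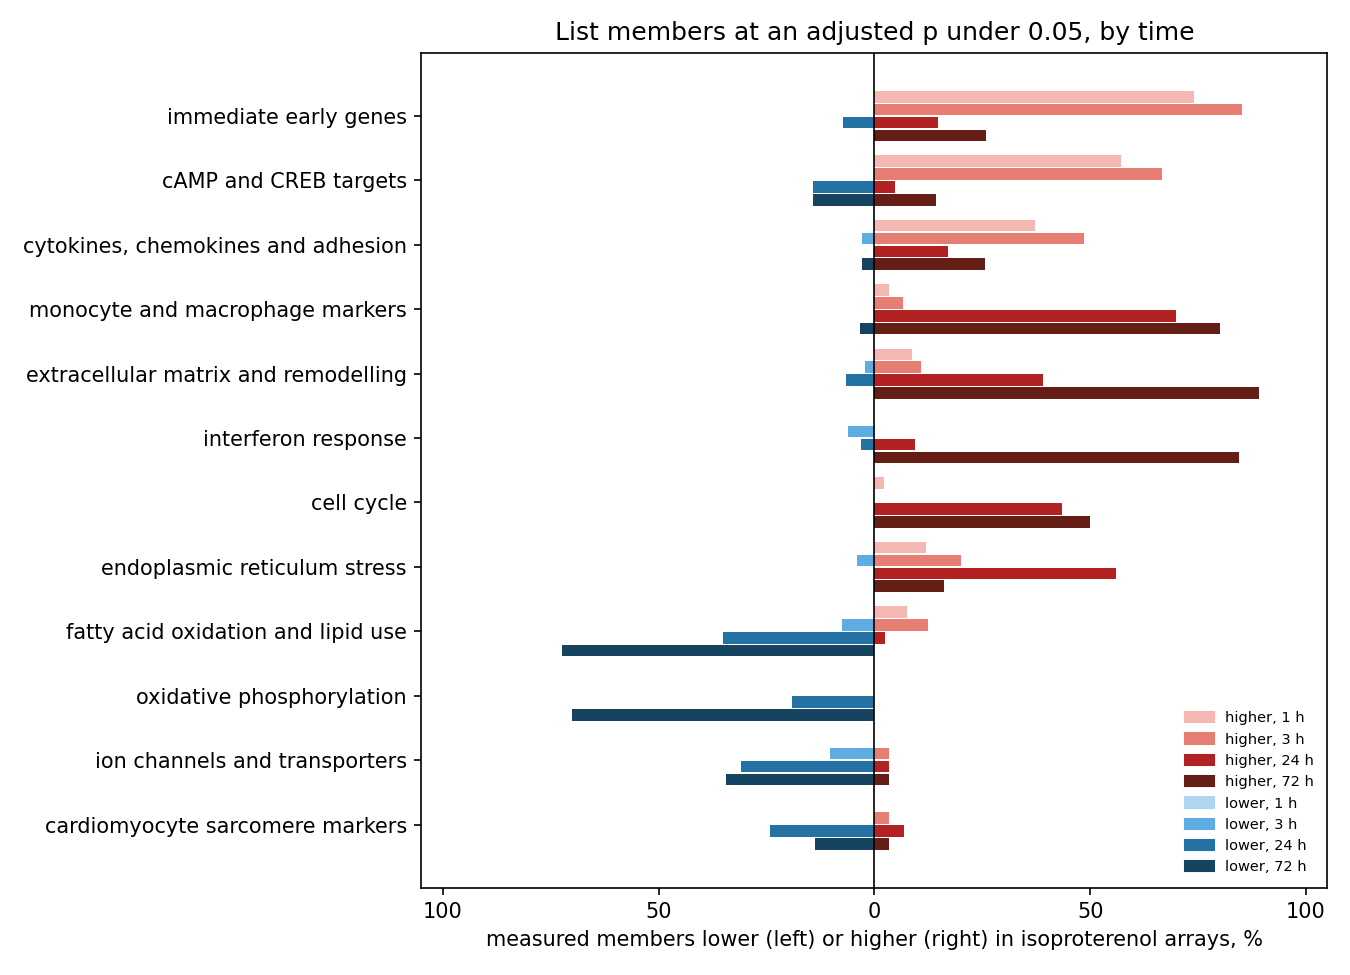
Percent of the measured members of 12 gene lists past the adjusted p threshold at each time, lower to the left and higher to the right, with darker bars for later times. Of 27 immediate early genes 20 were higher at 1 h and 23 at 3 h. At 72 h matrix genes (41 of 46) and interferon genes (27 of 32) were higher and fatty acid oxidation genes (29 of 40) were lower. Without normalization the fatty acid oxidation and oxidative phosphorylation lists had 0 lower calls at 24 and 72 h.

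At 72 h matrix, macrophage and interferon genes were higher. Postn rose by 5.23 ± 0.54 (37.6-fold, adjusted p = 8.83e-07, n = 5 and 3), Cthrc1, a secreted protein of activated fibroblasts, by 4.50 ± 0.63, and Gpnmb by 4.21 ± 0.47. For Postn, isoproterenol replicate 1 was at 9.52 and the others at 12.89 to 13.11, so the mean change lies below that of the others. Mpeg1, a perforin-like protein of macrophages, rose by 3.65 ± 0.42, the NADPH oxidase subunit Cybb by 3.42 ± 0.39 and the beta-glucan receptor Clec7a by 3.40 ± 0.40. Vehicle levels of Clec7a (4.68 ± 0.542, SD, n = 3), Cthrc1 (5.25 ± 0.637), Atf3 (4.96 ± 0.501) and Spp1 (4.68 ± 0.362) were as dim as the probe sets the filter leaves out, so the sizes of their changes at 72 h are best read as lower bounds. The largest falls were in Prkaa2, a catalytic subunit of AMP-activated kinase (-1.93 ± 0.34, adjusted p = 0.000170), the amino acid transporter subunit Slc3a1 (-1.91 ± 0.34) and Phlda1 (-1.60 ± 0.46). Phlda1 did not pass without vehicle replicate 1 (limma adjusted p = 0.0825) or 3 (0.160).

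Of 46 extracellular matrix genes, 41 rose, 0 fell and 5 did not pass, against 45 rising and 0 falling adjusted over the list alone (camera adjusted p = 1.36e-31, adjusted p = 0.0498 with an estimated correlation). Fibronectin (Fn1) rose by 2.93 ± 0.34, the collagens Col5a2 and Col1a1 by 2.46 ± 0.30 and 1.81 ± 0.33, and Timp1 by 2.90 ± 0.51. Of 30 monocyte and macrophage markers, 24 rose, 1 fell and 5 did not pass, against 26 rising and 1 falling adjusted over the list alone (camera adjusted p = 2.54e-19, adjusted p = 0.0742 with an estimated correlation). Spp1 rose by 3.21 ± 0.55, lysozyme (Lyz2) by 2.59 ± 0.28 and complement C1qa by 2.36 ± 0.25. Of 32 interferon response genes, 27 rose, 0 fell and 5 did not pass, against 29 rising and 0 falling adjusted over the list alone (camera adjusted p = 5.91e-18, adjusted p = 0.0498 with an estimated correlation). They included the class II molecule gene RT1-Da (2.34 ± 0.30), the transcription factor Irf7 (2.29 ± 0.36) and the immunoproteasome subunit Psmb9 (1.65 ± 0.22). Of 46 cell cycle genes, 23 rose, 0 fell and 23 did not pass, against 32 rising and 0 falling adjusted over the list alone (camera adjusted p = 6.16e-09, adjusted p = 0.246 with an estimated correlation). The proliferation marker Mki67 rose by 1.87 ± 0.37. Of 22 hypertrophy and fetal genes, 9 rose, 1 fell and 12 did not pass, against 10 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.00136, adjusted p = 0.134 with an estimated correlation). Nppa rose by 2.90 ± 0.49 and Myh7, the slow myosin heavy chain, by 1.67 ± 0.29, while Nppb did not pass (0.42 ± 0.23).

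Smaller upward shifts were in cytokine, immediate early and endoplasmic reticulum stress genes. Of 35 cytokine, chemokine and adhesion genes, 9 rose, 1 fell and 25 did not pass, against 10 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.0353, adjusted p = 0.567 with an estimated correlation). Cxcl10, a chemokine induced by interferon, rose by 2.91 ± 0.53 and Ccl2 by 1.27 ± 0.41. Ccl2 did not pass with a pseudocount of 64 (limma adjusted p = 0.0549), nor without vehicle replicate 1 or 3 or isoproterenol replicate 2, 3 or 5 (0.0608 to 0.136). Of 27 immediate early genes, 7 rose, 0 fell and 20 did not pass, against 9 rising and 0 falling adjusted over the list alone (camera adjusted p = 0.0353, adjusted p = 0.605 with an estimated correlation). Fos rose by 1.94 ± 0.44, Egr2 by 1.84 ± 0.35 and Atf3 by 1.54 ± 0.37 (limma adjusted p = 0.0501 without vehicle replicate 3). Of 25 endoplasmic reticulum stress genes, 4 rose, 0 fell and 21 did not pass, against 4 rising and 0 falling adjusted over the list alone (camera adjusted p = 0.0488, adjusted p = 0.593 with an estimated correlation). The disulfide isomerase gene Pdia4 rose by 1.17 ± 0.27, Sdf2l1 by 0.70 and Pdia3 by 0.59. Sdf2l1 did not pass without any 1 vehicle array or isoproterenol replicate 2, 3 or 4 (limma adjusted p 0.0595 to 0.146). Nor did Pdia3 without vehicle replicate 1 (0.115) or isoproterenol replicate 3 (0.0639). Egr1 (0.60 ± 0.35), Nr4a1 (0.12 ± 0.27), Il6 (0.26 ± 0.38), S100a9 (-0.78 ± 0.35), Hmox1 (0.96 ± 0.37, adjusted p = 0.0718) and Adrb1 (-0.40 ± 0.22) did not pass.

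Of 40 fatty acid oxidation and lipid genes, 0 rose, 29 fell and 11 did not pass, against 2 rising and 36 falling adjusted over the list alone (camera adjusted p = 2.07e-14, adjusted p = 0.138 with an estimated correlation). The dehydrogenase gene Hadh fell by 1.26 ± 0.22, the isomerase gene Ech1 by 1.03 ± 0.22, Pdk4 by 1.06 ± 0.29 and Ucp3 by 0.92 ± 0.27. Ucp3 was at -0.58 without vehicle replicate 1 and did not pass (limma adjusted p = 0.223), nor without isoproterenol replicate 2 (0.0504) or 3 (0.0607). Pdk4 did not pass without vehicle replicate 1 (0.0785), nor Ucp3, Pdk4 and Ech1 with only the arrays compared (limma adjusted p = 0.0717, 0.0936 and 0.0538). Of 47 oxidative phosphorylation genes, 0 rose, 33 fell and 14 did not pass, against 0 rising and 40 falling adjusted over the list alone (camera adjusted p = 2.03e-15, adjusted p = 0.203 with an estimated correlation). Sdhc, of complex II, fell by 0.67 ± 0.13 and Ndufa1, of complex I, by 0.59 ± 0.13. Of 29 ion channel and transporter genes, 1 rose, 10 fell and 18 did not pass, against 1 rising and 13 falling adjusted over the list alone (camera adjusted p = 0.000297, adjusted p = 0.244 with an estimated correlation). The potassium channel gene Kcnk3 fell by 1.12 ± 0.22. Of 29 sarcomere markers, 1 rose, 4 fell and 24 did not pass, against 1 rising and 4 falling adjusted over the list alone (camera adjusted p = 0.0116, adjusted p = 0.518 with an estimated correlation). Trdn, of the calcium release complex, fell by 0.93 ± 0.20, while Myh6 (-0.06 ± 0.07) and Pln (-0.04 ± 0.08) did not pass. Cox6a2 (-0.30) and Myl3 (-0.24) fell. Neither passed without vehicle replicate 1 or 3 or isoproterenol replicate 2 or 3 (limma adjusted p 0.0549 to 0.196). Des rose by 0.45 and did not pass under median centring (0.294) or trimmed mean scaling (0.595). With median centring 0 sarcomere markers rose and 15 fell (median -0.50), and with trimmed mean scaling 0 and 16 (-0.57), against a reported median of -0.11.

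Of 27 hypoxia and angiogenesis genes, 1 rose, 9 fell and 17 did not pass, against 1 rising and 11 falling adjusted over the list alone (camera adjusted p = 0.00126, adjusted p = 0.109 with an estimated correlation). Apln fell by 1.47 ± 0.26 and the growth factor gene Vegfa by 0.87 ± 0.19. Of 7 erythroid markers, 0 rose, 4 fell and 3 did not pass, against 0 rising and 5 falling adjusted over the list alone (camera adjusted p = 0.00112, adjusted p = 0.178 with an estimated correlation). The transferrin receptor gene Tfrc fell by 1.20 ± 0.22 and the globin gene Hbb by 0.42. Hbb did not pass without vehicle replicate 1 or 3 or isoproterenol replicate 2 or 4 (limma adjusted p 0.0621 to 0.108). Of 19 endothelial markers, 0 rose, 2 fell and 17 did not pass, against 0 rising and 2 falling adjusted over the list alone (camera adjusted p = 0.0488, adjusted p = 0.378 with an estimated correlation). Aqp1 fell by 0.70 ± 0.20 and Tie1 by 0.68 ± 0.20. Aqp1 did not pass without vehicle replicate 1 or 3 or isoproterenol replicate 3 (limma adjusted p 0.0537 to 0.127), nor with only the arrays compared (0.0868). Tie1 did not pass under median centring (0.0896), nor without any 1 vehicle array or isoproterenol replicate 3 (limma adjusted p 0.0509 to 0.0698). With centring 1 endothelial marker fell, at a median of -0.15 against -0.26.

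The falls at 72 h too are relative to the other transcripts. Without normalization the median of all probe sets was 0.36, and 2351 probe sets passed as higher and 29 as lower. The medians were then -0.26 for fatty acid oxidation, -0.15 for oxidative phosphorylation, -0.02 for sarcomere and -0.12 for erythroid genes, and 0.07 for ion channels, 0.18 for hypoxia and 0.32 for endothelial markers. Each of these 7 lists then had 0 lower calls. The beta-actin 3' minus 5' difference was 1.30 ± 0.417 (SD, n = 5) in isoproterenol arrays and 1.47 ± 0.555 (SD, n = 3) in vehicle arrays. For GAPDH it was 0.371 ± 0.0657 (SD) and 0.412 ± 0.1035 (SD).

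In all, 4354 probe sets passed at 72 h, 2275 higher and 2079 lower, for 1744 and 1357 genes. With arrays centred on their medians the median of all probe sets was -0.12. The count was 2436 without vehicle replicate 1, 2418 without vehicle replicate 3 and 2822 without isoproterenol replicate 3. Without the 2 arrays that stood apart, 5831 passed, with 44 matrix, 27 macrophage, 29 interferon, 31 cell cycle and 11 hypertrophy members higher. Lower were 35 fatty acid oxidation, 41 oxidative phosphorylation, 15 ion channel, 8 sarcomere, 11 hypoxia, 5 erythroid and 6 endothelial members. Of the 1781 probe sets higher at 24 h, 799 were also higher at 72 h, against 167 for independent lists. Of the 1384 lower at 24 h, 562 were lower at 72 h, against 118.

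**Figure D3:**
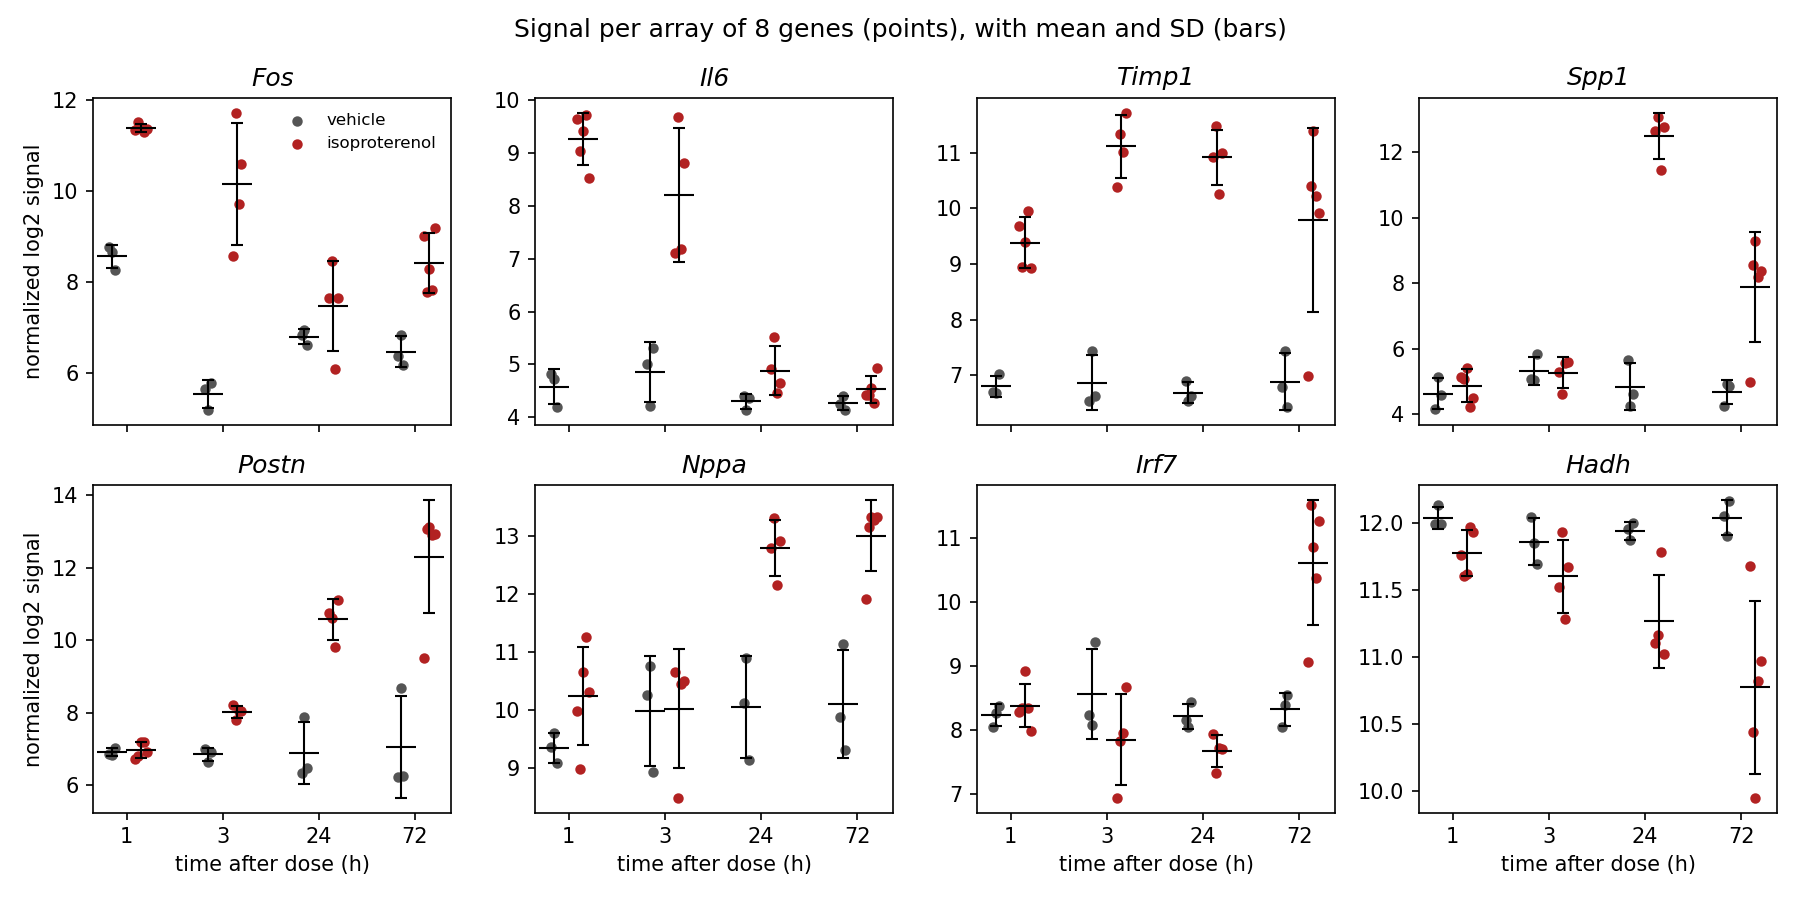
Normalized log2 signal of 8 genes in each array (points) with the group mean and SD (bars) against hours after the dose, vehicle in grey and isoproterenol in red. Fos and Il6 were highest in isoproterenol arrays at 1 and 3 h, Spp1 at 24 h, and Postn and Irf7 at 72 h. Hadh fell by 1.26 ± 0.22 at 72 h relative to vehicle.

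The effect itself differed between successive times for 141 probe sets from 1 to 3 h (95 higher and 46 lower at 3 h). From 3 to 24 h it differed for 1649 (872 and 777) and from 24 to 72 h for 514 (321 and 193). From 1 to 3 h the effect grew most for the adaptor gene Bcar1 (2.56 ± 0.41), the ribosome biogenesis gene Rrp12 (2.39 ± 0.45) and Sgk1 (2.01 ± 0.33). In the vehicle arrays Sgk1 was at 9.24 ± 0.730 (SD, n = 3) at 1 h and 7.66 ± 0.289 at 3 h, so a lower vehicle level makes up most of its gain. The effect decreased most for Ccdc102a (-1.94 ± 0.27), the protease gene Adamts6 (-1.82 ± 0.35) and the hormone gene Stc1 (-1.79 ± 0.29). In the isoproterenol arrays of 3 h Ccdc102a and Adamts6 were as dim as the probe sets the filter leaves out, so the sizes of their differences are uncertain. Without normalization none of these 6 genes passed (limma adjusted p 0.0686 to 0.558). Their differences were then 2.27 to 2.59 upward and -1.68 to -1.78 downward.

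From 3 to 24 h Spp1 (7.70 ± 0.81), Gpnmb (4.43 ± 0.69) and the class II molecule gene RT1-Bb (4.41 ± 1.25) gained most, and Nr4a3 (-5.65 ± 0.59), Fosb (-4.68 ± 0.39) and Fos (-3.94 ± 0.65) lost most. The dim vehicle levels of Spp1 at 24 h and Fosb at 3 h leave the sizes of their differences uncertain. RT1-Bb did not pass with robust variance (limma adjusted p = 0.0698), nor without vehicle replicate 1 or 2 or isoproterenol replicate 2 or 3 of 3 h (0.0528 to 0.0670), nor without vehicle replicate 1 or isoproterenol replicate 1 or 4 of 24 h (0.0503 to 0.0888). Of the 1484 probe sets higher at 3 h, 351 were higher at 24 h, against 109 for independent lists, and of the 1282 lower, 170 were lower, against 73.0.

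From 24 to 72 h the gains were largest for the fibronectin domain gene Fndc1 (3.83 ± 0.53), Cthrc1 (3.77 ± 0.91) and the interferon-induced Mx1 (3.72 ± 0.81). The losses were largest for Spp1 (-4.44 ± 0.79), the activin-binding Fstl3 (-2.20 ± 0.38) and the pseudogene Ddx3x-ps1 (-1.95 ± 0.38). The dim vehicle levels of Spp1 at both times and of Cthrc1 at 72 h leave the sizes of their differences uncertain. Cthrc1 did not pass without vehicle replicate 1 or 2 of 24 h or vehicle replicate 3 of 72 h (limma adjusted p 0.0594 to 0.0940), nor with a pseudocount of 1 or robust variance (0.0561 to 0.0578). With only the arrays compared Cthrc1 and Mx1 did not pass (limma adjusted p = 0.128 and 0.0838). Without normalization Fstl3 and Ddx3x-ps1 did not (0.0637 and 0.164), at differences of -2.30 and -2.01.

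These counts moved when single arrays were left out. From 1 to 3 h the count was 65, 89 and 66 without vehicle replicates 1, 2 and 3 of 1 h and 83 without vehicle replicate 1 of 3 h. From 3 to 24 h it was 1018 without vehicle replicate 2 of 3 h, and 1062 and 1043 without vehicle replicates 2 and 3 of 24 h. Leaving out isoproterenol replicates 2 and 3 of 24 h in turn gave 1063 and 2520. From 24 to 72 h the count was 220, 311 and 294 without vehicle replicate 2, vehicle replicate 3 and isoproterenol replicate 2 of 24 h. It was 186, 1110 and 186 without vehicle replicates 1, 2 and 3 of 72 h, and 883 and 341 without isoproterenol replicates 1 and 2 of 72 h. The direction of the differences followed the scaling from 3 to 24 h. From 1 to 3 h and from 24 to 72 h more were higher without normalization and with median centring too. Without normalization 5 higher and 0 lower, 1601 and 59, and 48 and 6 passed in order of time. With median centring 159 and 26, 511 and 1639, and 353 and 103 passed, and trimmed mean scaling gave 1429 and 686 from 3 to 24 h.

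Among the vehicle arrays, 24 probe sets differed between the 4 times in the limma F test. They named 7 genes: Klf2, Sgk1, Fos, Lactb, the clock gene Per2, Shoc2 and Atp6v0a1. Fos was at 8.57 ± 0.258 (SD, n = 3) in the vehicle arrays of 1 h, 5.54 ± 0.309 at 3 h, 6.80 ± 0.162 at 24 h and 6.47 ± 0.337 at 72 h (adjusted p = 0.0289). In the isoproterenol arrays of 1 h it was at 11.4 ± 0.0876 (SD, n = 5). The adjusted p for Sgk1 was 0.0289. Of 17 clock genes 1 passed, Per2, at 6.65 ± 0.0430 (SD, n = 3) at 3 h and 8.31 ± 0.458 at 24 h (adjusted p = 0.0392), and the adjusted p was 0.0755 for Bhlhe41 and 0.137 for Dbp.

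The vehicle count was 6, 3 and 5 without vehicle replicates 1, 2 and 3 of 1 h, and 7 and 126 without replicates 2 and 3 of 3 h. It was 6, 13 and 7 without replicates 1, 2 and 3 of 24 h, and 11, 114 and 12 without those of 72 h. Without normalization it was 7.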

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

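The tests of a vehicle array labelled as isoproterenol, of a dim array or degraded RNA, of scanner gain, of oxidative phosphorylation against sarcomere genes, of the fatty acid oxidation fall under other scalings, and of the differences between times by shuffled residuals were chosen after the result was seen. A sample far from the others of its group was looked for with Dixon's ratio in 314 groups of 4 or 5 isoproterenol arrays (named genes and array measures), and 25 groups had one, where chance gives about 1 in 20 groups. Its 95% critical value for the number of arrays was the limit.

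At 72 h, isoproterenol replicate 1 was lowest in 13 of 91 groups. The ratios were 0.939 (9.52 against 12.89 to 13.11) for Postn on the log2 scale, 0.866 for Cthrc1, 0.889 for Gpnmb, 0.724 for Mpeg1, 0.787 for Clec7a, 0.883 for Nppa and 0.744 for Spp1. They were 0.792 for Col1a1, 0.949 for Lyz2, 0.763 for Fn1, 0.755 for Col5a2, 0.744 for Pdia3 and 0.777 for RT1-Da. At 24 h, isoproterenol replicate 3 was lowest in Bcat1, 0.868 (7.13 against 8.09 to 8.23), Mcm6, 0.869 (7.41 against 8.32 to 8.46), and Mcm7, 0.884 (7.57 against 8.75 to 8.91). At 3 h, replicate 2 was lowest in Nppa, 0.909 (8.48 against 10.45 to 10.65), and highest in Hbegf, 0.866 (8.53 against 7.37 to 7.53), and Dnajb4, 0.839 (12.19 against 11.58 to 11.68). At 1 h, replicate 4 was highest in Mid1ip1, 0.805 (9.04 against 8.26 to 8.41), and Rgs2, 0.846 (10.80 against 10.30 to 10.37), and lowest in Crem, 0.809 (10.66 against 11.21 to 11.33), and in the beta-actin 3' minus 5' difference, 0.723 (1.47 against 1.86 to 2.01). Replicate 2 of 1 h was lowest in Gdf15, 0.761 (5.51 against 5.80 to 5.90), and replicate 5 highest in Hmmr, 0.799 (5.40 against 5.21 to 5.25).

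The first pattern weighed is that isoproterenol replicate 1 at 72 h lies nearer the vehicle arrays than the other 4 do. The tables argue against a dim array or degraded RNA, since 0 of 4 quality measures lay outside the range of the other 29 arrays. For an array of 24 h labelled 72 h, the share of the change particular to 24 h was taken. This array held -0.163 of it, the other 72 h isoproterenol arrays -0.0069 to 0.27 and the 24 h ones 0.555 to 1.47. The probe sets were picked for a difference between 24 and 72 h, with this array included. That favours a low share in advance, so a wrong time label stays open. A smaller change of the same genes in this heart stays open: over 1886 probe sets changed at least 2-fold without it, 91.7% moved in the direction of the other 4 arrays, where the vehicle arrays had 34.1%, 71.9% and 32.4%. A vehicle array labelled as isoproterenol stays open too, since the array held 0.323 of the change, above the 3 vehicle arrays (-0.129 to 0.196) and below the other isoproterenol arrays (0.802 to 1.27), and 27.2% of those probe sets lay beyond all 12 vehicle arrays, against 1.48% to 17% for a vehicle array judged by the other 11. The 3 vehicle arrays of 72 h are too few to settle whether the label is wrong.

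The second pattern is the fall of fatty acid oxidation and oxidative phosphorylation genes at 72 h. A lower share of cardiomyocyte RNA as the whole cause would lower sarcomere genes as much. In the same signal range 28 fatty acid members changed by -0.70 ± 0.32 (SD) and 10 sarcomere members by -0.24 ± 0.37 (SD, permutation p = 0.00076 over 100000 resamples). The permutation exchanges genes measured on the same arrays, so this p and those below take no account of the spread between hearts. They therefore do not decide on that share. For 24 oxidative phosphorylation members the mean was -0.46 ± 0.18 (SD, permutation p = 0.0239 against the sarcomere members, 0.0217 with median centring and 0.0228 with trimmed mean scaling). The difference between fatty acid and sarcomere members was -0.46, and it was -0.36 with median centring (permutation p = 0.00679) and -0.35 with trimmed mean scaling (permutation p = 0.00711). RNA integrity at 72 h is argued against as far as beta-actin measures it, since the groups differed by only -0.175. The slope on that difference implies -0.00986 of the observed change (-0.0218 to -0.00464 leaving out each array in turn). RNA integrity was not tested in this way at 24 h, where the groups differed more in beta-actin (0.872 against 1.64). The GAPDH 3' minus 5' difference at 24 h was 0.298 in isoproterenol arrays and 0.381 in vehicle arrays. A change in cardiomyocytes themselves was not tested.

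The third pattern is that isoproterenol arrays of 24 h are brighter on average before normalization. Replicates 1, 2 and 4 had log2 medians of 6.20 to 6.43. Replicate 3, at 5.68, lay within the vehicle arrays (5.51 to 6.03). Medians differed by 0.50 and hybridization controls by 0.19, a ratio of 0.376, and with 4 and 3 arrays a gain of the scanner or the hybridization stays open. Of all probe sets 87% were higher, and the median change was 0.47 in the brightest 10% and 0.47 in all. A rise of about the same size in all transcripts stays open as well, and the 2 cannot be told apart here. The beta-actin 3' minus 5' difference was also lower on average in the isoproterenol arrays than in the vehicle arrays (0.872 against 1.64). It was 0.550 to 0.86 in isoproterenol replicates 1, 2 and 4. In replicate 3 it was 1.40, within the vehicle arrays (1.37 to 1.855). The GAPDH difference was 0.298 against 0.381. Replicate 3 also lay nearest the vehicle arrays on component 1. Brightness, the beta-actin difference and the size of the change therefore cannot be told apart among these 4 arrays. RNA integrity was not tested as a cause of the brightness.

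Differences of the isoproterenol effect between successive times were tested directly. From 1 to 3 h, 141 probe sets differed, led by Bcar1 (2.56), Rrp12 (2.39) and Sgk1 (2.01) upward and Ccdc102a (-1.94), Adamts6 (-1.82) and Stc1 (-1.79) downward. From 3 to 24 h, 1649 differed, led by Spp1 (7.70), Gpnmb (4.43) and RT1-Bb (4.41), and by Nr4a3 (-5.65), Fosb (-4.68) and Fos (-3.94). From 24 to 72 h, 514 differed, led by Fndc1 (3.83), Cthrc1 (3.77) and Mx1 (3.72), and by Spp1 (-4.44), Fstl3 (-2.20) and Ddx3x-ps1 (-1.95). The sizes for Ccdc102a, Adamts6, Spp1, Fosb and Cthrc1 are uncertain, because of the dim levels given above.

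Other splits of the same arrays into groups of the same sizes were counted, and 100 were drawn at random where there were more. At 1 h, 1 of 56 splits, the real split, gave as many calls (643, highest other 5), and chance is excluded at 0.05. At 3 h it was 1 of 35 (2766, highest other 1479) and at 72 h 1 of 56 (4354, highest other 4160), and chance is excluded at 0.05 at both. At 24 h it was 2 of 35 (3165, highest other 4281), so chance is not excluded there. The shares at 1, 3 and 72 h are the smallest that so few splits can give. They were not adjusted over the results tested. The higher split at 24 h sets isoproterenol replicates 1, 2 and 4 against the vehicle arrays with isoproterenol replicate 3, and the 72 h split nearest the real count sets isoproterenol replicates 2, 3 and 5 against the other 5 arrays.

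For the differences between times these splits exchange treatment within a time. That takes away or turns the treatment effects, which equal effects at both times would keep, so their counts do not decide on chance. They were 3 of 100 splits from 1 to 3 h (141, highest other 364), 2 of 100 from 3 to 24 h (1649, highest other 5001) and 12 of 100 from 24 to 72 h (514, highest other 4946), and the highest split of each swaps all 3 vehicle arrays of 1 time with isoproterenol arrays. For chance with treatment and time effects kept, the residuals of a fit with these effects alone were shuffled between the arrays of the 2 times. As many calls came in 1, 1 and 2 of 100 draws, the real one included, with 15, 816 and 629 calls in the highest other draw. This test takes the spread to be the same in all arrays. The 2 arrays that stood apart, of 24 and 72 h, go against equal spread. So do the vehicle arrays of 1 and 3 h. On component 2 they lay between 18.01 and 19.43 at 1 h and between 16.67 and 30.07 at 3 h. The test therefore does not decide on chance from 1 to 3 h, from 3 to 24 h or from 24 to 72 h.

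Among the vehicle arrays it was 12 of 100 splits (24, highest other 586), and chance is not excluded. Some splits there gave several times the real count, and the cause was not tested. For any isoproterenol effect it was 1 of 100 splits (7769, highest other 936), and chance is excluded.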

How the results depend on the processing

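Trimmed mean scaling, the filter on normalized values, the GAPDH covariate and leaving out the 2 arrays that stood apart were chosen after seeing the data. Counts below are probe sets past the threshold, in order of time for the 4 comparisons with vehicle. Counts of all 9 results stayed within 1.5 times the reported count with pseudocounts of 1 and 64, median centring, a filter at the 60th percentile, robust variance, trimmed mean scaling and the filter on normalized values.

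Without normalization between arrays the count was 190 at 1 h, 478 at 3 h and 2380 at 72 h, 5 from 1 to 3 h, 54 from 24 to 72 h, 7 among vehicle arrays and 4849 for any effect. In that setting 79 named gene results lost their call and 2 turned at 24 h, Idh3b to 0.07 (0.069) and Sdhc to 0.08 (0.084). This setting leaves the differences between array medians in the values by construction. With array weights the count was 1698 at 1 h, 5251 at 24 h and 7208 at 72 h, 493, 2915 and 1983 for the successive differences and 1128 among vehicle arrays, and the cause was not tested. With only the arrays compared in the fit it was 1313, 1331, 2104 and 2398, 246, 1022 and 133 for the differences, and 6 among vehicle arrays, and the cause was not tested. A 2-fold threshold left 337, 1018, 997 and 1409, 12 among vehicle arrays and 2781 for any effect.

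Without the 2 arrays that stood apart the count was 4778 at 24 h, 281, 3084 and 1054 for the differences and 56 among vehicle arrays. The vehicle count was 15 without a filter, 10 without an intensity trend and 66 with the GAPDH covariate, and the cause was not tested. Of 46 list calls, 19 passed with an estimated correlation between genes, and with the mean of a gene's probe sets 3 list calls ended. The estimates lay between -0.011 for lymphocyte and mast cell markers and 0.529 for extracellular matrix genes, against the preset 0.01.

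Leaving out each array in turn gave 392 to 606 at 1 h, 1871 to 3027 at 3 h, 1576 to 4417 at 24 h and 2418 to 5658 at 72 h. The differences gave 65 to 198, 1018 to 2520 and 186 to 1110, the vehicle arrays 3 to 126, any effect 6567 to 8533 and the lists 42 to 48. Among the named genes 122 results lost their call, 11 gained one and 2383 stayed on their side of the threshold.

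With the replicate number as a replicate block the count was 543, 2426, 2621 and 3620. Of 12 vehicle and isoproterenol pairs with the same number 2 had a correlation over 0.1 (-0.0739 to 0.125). For 5 of 12 vehicle arrays the best match was the array with their own number. They included vehicle replicates 1, 2 and 3 of 3 h (correlations 0.0347, 0.073 and 0.118). The correlations are low, and the check does not settle whether the numbers pair the arrays. Signal limits the dim probe sets: between 21.8% and 43.0% lay below an intensity of 16, the pseudocount, on an array.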

Other observations

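The genes named in this part were chosen after their values were seen, from lists with no camera call at that time, and each passed the threshold at the time given. The glycolysis list held 3 higher and 5 lower of 27 genes at 24 h (camera adjusted p = 0.213) and 2 and 6 at 72 h (0.0622). At 24 h the platelet phosphofructokinase gene Pfkp rose by 1.52 ± 0.31 and the liver phosphorylase gene Pygl by 0.89 ± 0.26, while the muscle forms Pfkm (-0.75 ± 0.16) and Pygm (-0.50 ± 0.17) and the insulin-responsive glucose transporter Slc2a4 (-0.85 ± 0.24) were lower. At 72 h Pfkp was at 1.07 ± 0.30 and Pygl at 1.20 ± 0.25, and Pfkm (-0.61 ± 0.15), Pygm (-0.65 ± 0.16), Slc2a4 (-1.01 ± 0.23) and hexokinase Hk2 (-0.91 ± 0.27) were lower. Without normalization the list median was 0.29 at 24 h and 0.23 at 72 h, against -0.13 and -0.11, and 0 members were lower at either time. With trimmed mean scaling 10 were lower at 72 h.

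The circadian clock list had 4 higher and 4 lower of 17 genes at 3 h (camera adjusted p = 0.817). Bhlhe40 (1.36 ± 0.25), Nfil3 (1.29 ± 0.20), Per2 (1.12 ± 0.26) and Cry2 (0.85 ± 0.23) were higher, and the output factors Dbp (-1.70 ± 0.37) and Tef (-0.72 ± 0.21) and the nuclear receptors Nr1d1 (-1.19 ± 0.20) and Nr1d2 (-1.27 ± 0.23) were lower. The rise of Per2 came with its lowest vehicle level, 6.65 at 3 h against 7.46, 8.31 and 7.36 at 1, 24 and 72 h. The list median was -0.27 at 3 h and -0.44 without normalization, where 0 genes were higher and 3 lower.

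Of 25 beta-adrenergic signalling genes, 3 were higher and 6 lower at 72 h (camera adjusted p = 0.0892). The protein kinase A subunit Prkaca (-1.15 ± 0.23), the anchoring protein gene Akap6 (-1.01 ± 0.26), the phosphodiesterase gene Pde4d (-0.84 ± 0.25) and the adenylyl cyclase gene Adcy5 (-0.48 ± 0.16) were lower, and Pde3b (1.01 ± 0.27), Rgs2 (0.92 ± 0.27) and Arrb2 (0.78 ± 0.26) higher. The median was -0.17, and 0.24 without normalization, where 4 were higher and 0 lower. With median centring 4 were lower.

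Of 22 fibroblast and mural cell markers, 10 were higher and 1 lower at 72 h (camera adjusted p = 0.0622), among them Thy1 (3.04 ± 0.45), S100a4 (2.85 ± 0.37), Tagln (2.35 ± 0.38) and Acta2 (0.99 ± 0.34). Adipocyte markers had 2 higher and 4 lower of 13 at 72 h (camera adjusted p = 0.121), with Cfd at 1.59 ± 0.32 and Fabp4 at -0.88 ± 0.23. Endothelial markers at 3 h had 4 higher and 4 lower of 19 (camera adjusted p = 0.329), with Cldn5 at 1.10 ± 0.25 and Tie1 at -1.28 ± 0.21. At 72 h lymphocyte and mast cell markers had 2 higher and 0 lower of 21 (0.720), and skeletal muscle markers 1 and 1 of 14 (0.941). At 24 h atrial, mesothelial and nerve markers had 3 higher and 2 lower of 17 (0.902). Without normalization the adipocyte median at 72 h was -0.05 (reported scaling -0.35) and the endothelial median at 3 h 0.36 (reported scaling 0.37), with 0 adipocyte markers lower, and 0 endothelial markers higher and 1 lower. At 3 h the endothelial split was 7 higher and 2 lower with median centring (median 0.63) and 6 and 4 with trimmed mean scaling (0.45).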
